A study of Zea mays with 16 samples.

How the data were processed

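RNA from whole maize anthers of 1.5 mm was measured on 8 two-colour Agilent arrays, held on 2 slides of 4 arrays each. Every array carried 2 samples, 1 labelled with Cy3 and 1 with Cy5, which made 16 samples in 4 groups. Per the labels, 6 samples came from ms23 mutants, 2 from fertile siblings of the ms23 family, 6 from ms32 mutants and 2 from fertile siblings of the ms32 family. The 4 arrays of slide 1 each held an ms23 mutant against an ms32 mutant. On slide 2, arrays 1 and 2 held an ms32 mutant against an ms32 fertile sibling, and arrays 3 and 4 held an ms23 mutant against an ms23 fertile sibling. Each pair of arrays that shared replicate numbers carried the dyes in opposite orientation.

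Per the labels' protocols, total RNA was extracted from frozen tissue, treated with DNase, amplified and labelled. Per the file headers, the arrays were of Agilent design 016047 and the images were quantified with Feature Extraction 10.5.1.1. The deposited scanner files give, for each spot and dye, linear intensity values of the spot and of its local background, an intensity processed by the scanner software, and marks of 0 or 1 for outliers, saturation and spots well above background. A table of processed intensity values, 1 column per sample, was also deposited; the submitters' processing notes name Agilent Feature Extraction and limma, and the normalization is not given in the sources used here. Column medians of that table lay between 117.6 and 117.7, and between 11.4% and 33.3% of a column's values were listed at 0. On the log2 scale its positive values correlated across probes with the scanner software's processed signals of the same sample at 0.969 to 0.981, with slopes of 0.725 to 0.821. The dye labels settle the direction of that table, its scale is linear, and how it was centred and why values were set to 0 stay unknown.

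The scanner files were analysed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Median spot and background intensities were used, because the scanner files as used here give no mean intensities, which the plan had named. Background was corrected by the normexp method with an offset of 50, fitted on all spots. Log2 ratios of Cy5 over Cy3 were normalized by loess within each array, with weight 0 for control spots and for spots that the scanner software marked as non-uniform or population outliers. Such spots numbered 1322 over the arrays and stayed out of the fits. No scaling between arrays was applied. The 1417 control spots were then left out, which left 42034 probes with 39174 target names. A probe was tested if it was well above background in at least 50% of the samples of at least 1 group, read in the dye that held the sample; 39981 probes passed and 2053 were not tested.

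A single limma model was fitted to the ratios of all 8 arrays, turned to mutant over fertile sibling or to ms23 mutant over ms32 mutant, with a dye term for each probe and moderated variances. The 3 ratios measured on shared arrays were the model's coefficients. The difference of the mutant effects, ms23 minus ms32, and the ratio of the fertile siblings of the 2 families were sums of these coefficients. Benjamini-Hochberg adjustment was made over the probes of each comparison, and a probe was called at an adjusted p under 0.05. The comparisons with their limma tests, the filter and most alternatives were fixed before the data were examined, whereas most tests of explanations were chosen later.

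The series text speaks of 2 biological replicates per comparison of mutant and sibling, whereas the titles give both dye-swapped arrays of such a comparison the same replicate number. The arrays with the same replicate numbers were therefore a random block in the model. The consensus correlation within blocks was -0.277, and 0 was used in its place, so that each array counted as independent. If the dye-swapped arrays shared RNA, the p-values measure the technical spread between arrays and not that between plants. The residual degrees of freedom were 4 and the prior degrees of freedom 1.95.

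The model was tested on simulated arrays with 39981 probes, of which 200 per comparison were changed. With independent arrays, 44.8% of the changes of 1 on the log2 scale, 83.6% of those of 2 and 100% of those of 4 were called for the ms23 mutant against its sibling. The same shares were 53.7%, 80.6% and 98.5% for the ms32 mutant against its sibling, and 83.6%, 95.5% and 100% for the ms23 mutant against the ms32 mutant. False calls made up 5%, 7.19% and 5.1% of the calls in these 3 comparisons. When arrays of a block were simulated with a correlation of 0.25, the fit used 0, as for the real arrays. False calls then made up 15.7%, 13.8% and 19.2%. With a simulated correlation of 0.5, where the fit used 0.222, they made up 20%, 23% and 18.5%. The block correlation was estimated too low in these simulations: independent arrays gave -0.323, a correlation of 0.25 gave -0.0659 and a correlation of 0.5 gave 0.222.

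Between 81.19% and 94.79% of the probes were well above background in a sample, the median spot intensity was 2.68 to 6.11 times the median background, and 0 spots were saturated. The number of arrays limits the precision.

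Targets are named as in the scanner files. Most names are those of sequence contigs or single database entries, and 4 probes of 2 genes matched a name in the RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0. Of 24 gene lists fixed in advance, 1 had a measured member, the meiosis list with the gene AM1, so no list held the minimum of 5 genes for a list test and none was run. No probe was named for ms23 or ms32, so the levels of the mutated genes are not analysed here. As fixed in advance for files that do not pair probes with genes, at most 2 probes that rose and 2 that fell are named per comparison: those with the largest change among called probes that had the same sign on every array of the comparison. The same-sign condition was not applied to the 2 comparisons that are sums of ratios. Probes named for meiotic, cohesin and MuDR transposon genes were grouped by name after the target names were read.

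Alternatives covered the background correction, the normalization, the filter, the dye term, the replicate block, each slide alone, the variance model, the deposited processed table, and each array left out. Alternatives chosen after seeing the data were 3 choices of a pair of slide 1 arrays and a crossed replicate block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.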

Results

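Gene expression was compared in whole anthers of 1.5 mm from maize plants of 2 male-sterile families. The ms23 and ms32 loci each encode a basic helix-loop-helix transcription factor needed for the tapetum, the anther cell layer that nourishes developing pollen, and the series concerns how MS23 governs the formation and maturation of that layer. The 16 samples comprised 6 of ms23 mutants, 2 of ms23 fertile siblings, 6 of ms32 mutants and 2 of ms32 fertile siblings, hybridised in pairs to 8 two-colour arrays. These are labelled samples: the titles number 3 replicates of each mutant and 1 of each fertile sibling, each labelled with both dyes, so the spread behind a ratio to siblings may be technical. A ratio of a mutant to its fertile sibling rested on 2 arrays with the dyes swapped, and the direct ratio of the 2 mutants rested on 4. Those 4 arrays held 2 replicate numbers of each mutant, each with the dyes swapped, so their spread may also be in part technical. Median spot intensities of the samples ranged from 94 to 232.25, and between 81.19% and 94.79% of probes were well above background.

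With loess normalization, falls outnumbered rises among the probes called between ms23 mutants and their fertile siblings. Of 39974 probes, 371 were lower and 154 higher in the mutants (limma, adjusted p under 0.05; n = 2 arrays), and the fallen probes had a median log2 ratio of -1.83 against 1.37 for the risen ones. At least 8-fold falls numbered 84 and rises of that size 7; at least 32-fold falls numbered 22, with no rise that large. The transcript TC299638 fell by 7.19 on the log2 scale (SE 0.863, limma adjusted p = 0.0259) and TC283808 fell by 7.08 (SE 0.235, limma adjusted p = 0.000325), both on each of the 2 arrays. TC283808 was well above background in both ms23 fertile samples and in 4 of the 6 ms23 mutant samples, so the size of its fall is uncertain. The largest rises were those of TC295588, with a log2 ratio of 4.08 (SE 0.577, limma adjusted p = 0.0399), and TC280520, with 3.78 (SE 0.451, limma adjusted p = 0.0254). TC295588 had ratios of 5.08 and 3.07 on the 2 arrays, whereas TC280520 had 3.80 and 3.77. In ms32 mutants TC299638 had a ratio of -5.59, TC295588 of 1.98 and TC280520 of 2.49, all short of the threshold (limma adjusted p = 0.0905, 0.398 and 0.141). On the arrays that held both mutants, TC295588 was lower in ms23 than in ms32 mutants, at -1.58 (limma adjusted p = 0.0435).

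At an unadjusted p under 0.05 falls made up 53.9%, with 2502 lower and 2144 higher. The excess of falls also depended on the normalization: with median centring in place of loess, 493 probes were higher and 265 lower, and 35% of the calls were then falls in place of 70.7%. With every other normalization tried, falls made up 63.5% to 74.8% of the calls. Calls dropped to 34 when dye-swapped arrays were averaged into 1 replicate, to 48 and 71 without slide 2 array 4 or array 3, to 242, 244 and 259 without slide 1 array 3, 2 or 1, and to 0 in limma on slide 2 alone, where 4463 probes had an unadjusted p under 0.05; with scaling between arrays they rose to 928.

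Nearly all probes called between ms32 mutants and their fertile siblings were falls. Of 39976 probes, 182 were lower and 14 higher (limma, adjusted p under 0.05; n = 2 arrays), a share of falls of 92.9% that stayed between 89.6% and 95.1% over the other normalizations. At an unadjusted p under 0.05 the excess was smaller, with 1948 lower and 1177 higher (62.3% falls). The fallen probes had a median log2 ratio of -2.47, and 65 of them fell at least 8-fold, a size that no rise reached. The transcript DN227504 fell by 7.35 (SE 0.256, limma adjusted p = 0.000472) and AW520047 fell by 7.05 (SE 0.17, limma adjusted p = 0.000199). AW520047 also fell by 6.97 in the ms23 mutants (limma adjusted p = 0.000174), where it was well above background in 5 of 6 mutant samples. Among the rises, TC310653 had a log2 ratio of 2.98 (SE 0.379, limma adjusted p = 0.0496) and was also higher in the ms23 mutants, at 2.64 (limma adjusted p = 0.0414). TC313690 had a ratio of 1.73 (SE 0.222) with a limma adjusted p of 0.05 after rounding, just inside the threshold, and ratios of 1.05 and 2.41 on the 2 arrays.

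The log ratios of the 2 ms32 arrays correlated across probes at 0.132, below the 0.52 of the 2 ms23 arrays. Probes are not independent replicates. The dye term was not taken out of these ratios, and a dye effect lowers the correlation of dye-swapped arrays, as both pairs were. Limma called 0 probes with dye-swapped arrays averaged (3384 at an unadjusted p under 0.05) and 0 on slide 2 alone (3057), 67 and 76 without slide 2 array 1 or 2, 104, 113 and 123 without slide 1 array 3, 2 or 4, and 116 without slide 2 array 3 or 4; a dye term per slide gave 129, an offset of 10 gave 298 and an intensity trend with robust variances 310.

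**Figure D1:**
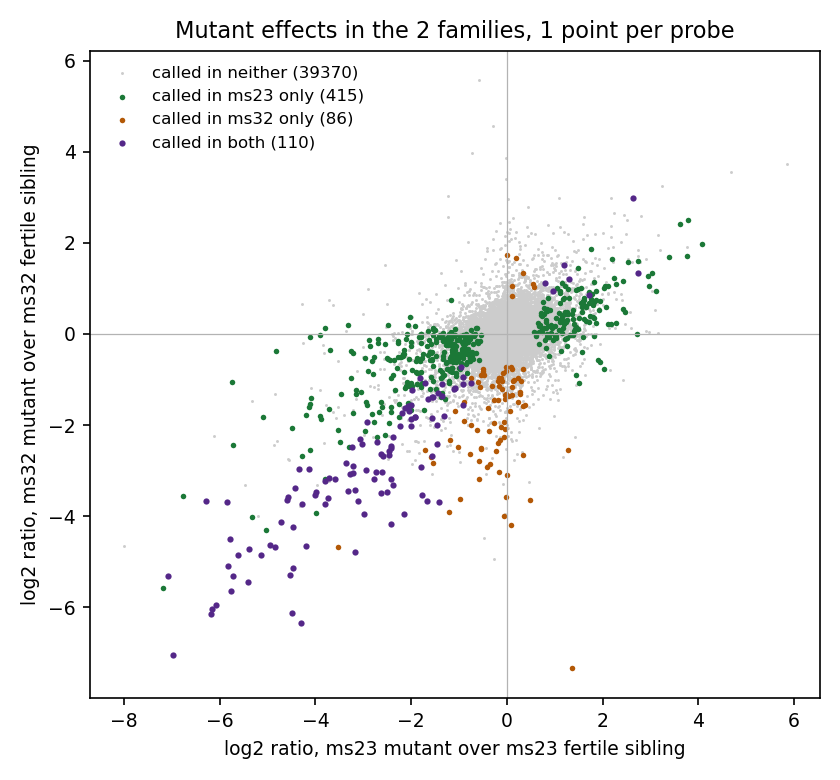
Each point is a tested probe, with the log2 ratio of ms23 mutant over ms23 fertile sibling on the horizontal axis and that of ms32 mutant over ms32 fertile sibling on the vertical axis; colours mark probes called in ms23 only (415), ms32 only (86) or both (110). The probes called in both lie mainly in the lower left corner, where both ratios are negative.

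Many of the same transcripts fell in both families. Of the 182 probes lower in ms32 mutants, 103 were also lower in ms23 mutants, where independent lists would share 1.69, and 7 probes were higher in both against an expectation of 0.0539. Both lists used the same variance for each probe, so they are not independent and these expectations may be too low. Limma called 0 probes in opposite directions; at an unadjusted p under 0.05 in both comparisons, 29 were lower in ms23 and higher in ms32 mutants and 55 the reverse, beside 797 lower in both and 457 higher in both. TC283808, which fell by 7.08 in ms23 mutants, fell by 5.31 in ms32 mutants (limma adjusted p = 0.00113), where it was also well above background in 4 of 6 mutant samples and the size is uncertain. AW520047 fell by about as much in each. The 103 shared falls had a median log2 ratio of -2.77 in ms23 and -3.05 in ms32 mutants. On the arrays that held both mutants together, the same 103 probes had a median ratio of ms23 over ms32 of -0.02.

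The 268 probes that were called lower in ms23 mutants alone had a median ratio of -0.51 in ms32 mutants, with 247 of them negative. The 79 called lower in ms32 mutants alone had a median of -0.16 in ms23 mutants. Of the 147 probes called higher in ms23 mutants alone, 121 had positive ratios in ms32 mutants, with a median of 0.42. Over all probes, the 2 mutant effects correlated at 0.524 (Pearson) and 0.292 (Spearman) across probes, which are not independent replicates. The 2 comparisons shared no sample. With dye-swapped arrays averaged, or on slide 2 alone, no probe was called in both; without 1 array the 110 shared calls became 80 (slide 1 array 1), 65, 62 and 73 (slide 1 arrays 2, 3 and 4), or 39, 50, 47 and 36 (slide 2 arrays 1 to 4).

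**Figure D2:**
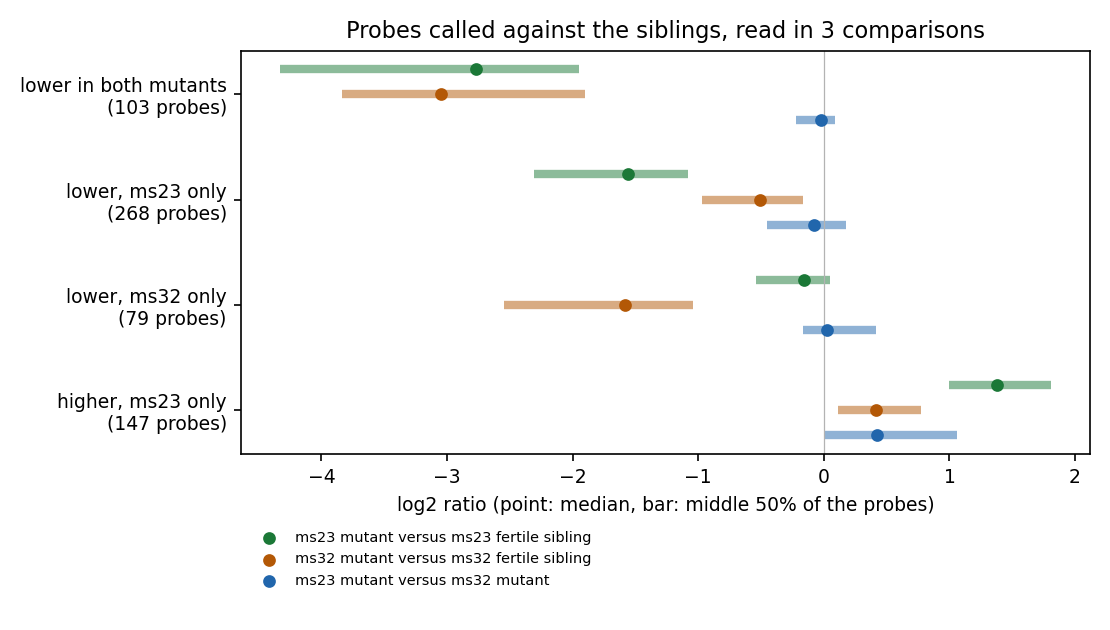
Points are medians and bars the middle 50% of the log2 ratios of 4 sets of probes, read as ms23 mutant over ms23 sibling, ms32 mutant over ms32 sibling and ms23 mutant over ms32 mutant. The 103 probes lower in both mutants lie near 0 in the direct ratio of the mutants, and the 147 higher in ms23 mutants alone lie above 0 in all 3.

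The direct comparison asked how anthers of the 2 mutants differ from each other. They differed at far more transcripts than either mutant differed from its siblings: 3803 of 39981 probes were higher and 4424 lower in ms23 than in ms32 mutants (limma, adjusted p under 0.05; n = 4 arrays), or 20.6% of the probes. Most of these differences were small, with median log2 ratios of 0.82 and -0.75, but 248 probes were at least 8-fold higher and 186 at least 8-fold lower. The transcript TC298763 had a log2 ratio of 7.48 (SE 0.172, limma adjusted p = 2.14e-05) and was well above background in 6 of 6 ms23 and 4 of 6 ms32 mutant samples, so the size of this ratio is uncertain too. TC280899 was 168-fold higher (SE of the log2 ratio 0.267, limma adjusted p = 5.73e-05). It was well above background in 5 of 6 ms32 mutant samples, so this size is also uncertain. In the other direction, AI737914 had a ratio of -6.58 (SE 0.437, limma adjusted p = 0.000395) and TC304850 one of -6.46 (SE 0.28, limma adjusted p = 9.8e-05). None of these 4 transcripts passed the threshold against the siblings of either family; their log2 ratios there ranged from -0.25 for TC298763 to 0.37 for AI737914, both in ms23 mutants. For TC298763 the ms32 arrays could not show a fall, since it was well above background in 0 of 2 ms32 fertile samples.

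A group of 24 probes was called lower in ms23 mutants and was not well above background in any ms23 mutant sample while well above it in every ms32 mutant sample, and 16 probes showed the reverse. The 4 arrays correlated with each other at 0.654 to 0.814 across probes, which are not independent replicates. With median centring in place of loess, 2067 probes were higher and 5040 lower, a share of lower probes of 70.9% in place of 53.8%. With dye-swapped arrays averaged 4392 probes were called, and without slide 1 array 3 or array 4 the count was 4459 or 5026.

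Of 4 probes named for the MuDR transposon, an autonomous element of the maize Mutator family, 3 were lower in ms23 than in ms32 mutants: MUDR-TIRA at -2.32 (95% confidence interval -2.57 to -2.07, limma adjusted p = 0.000105), MUDRB 2.01-fold lower (limma adjusted p = 0.032) and MUDRA-21 at -0.76 (limma adjusted p = 0.0295), each with the same sign on all 4 arrays. The remaining probe, MUDRA, had a ratio of -0.19 (limma adjusted p = 0.524). MUDR-TIRA stayed past the threshold in all 26 alternatives that measured it, whereas MUDRB lost it in 11 and MUDRA-21 in 10. Against the fertile siblings, limma called 0 of the 4 probes in either mutant, with 1 in each at an unadjusted p under 0.05. Adjusted over the 4 probes alone, a group formed after the names were read, limma called 1 lower in ms32 mutants, MUDR-TIRA, and 0 in ms23 mutants. MUDR-TIRA had ratios there of -0.44 in ms23 (limma adjusted p = 0.309) and -0.85 in ms32 mutants (limma adjusted p = 0.126).

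Limma called no change at the probes of meiotic and cohesin genes. The 17 probes of this group were named for AM1, which is required for entry into meiosis, for the cohesin subunits ZmRAD21, ZmSMC1 and ZmSMC3, and for ZmSGO1, a protector of centromeric cohesion. A ZmRAD21 probe among them (A_92_P009368) was well above background in 0 ms23 samples, 1 of 6 ms32 mutant and 1 of 2 ms32 fertile samples, so its ratios measured no change either way. Limma called 0 of the 17 in any comparison; at an unadjusted p under 0.05 there were 0 in ms23 mutants and 1 in ms32 mutants against siblings, and 1 in the direct comparison. Their log2 ratios lay between -0.03 and 0.44 in ms23 mutants, between -0.30 and 0.29 in ms32 mutants and between -0.33 and 0.60 in the direct comparison. The 95% confidence intervals reached from -0.644 to 1.1 in ms23 and from -0.784 to 0.858 in ms32 mutants, and from -0.705 to 1.15 in the direct comparison. AM1, recorded as gene LOC100271891 in the RefSeq table, was the single measured member of the meiosis list fixed in advance; adjusted over the list alone, 0 of its 3 probes passed, as over all probes.

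**Figure D3:**
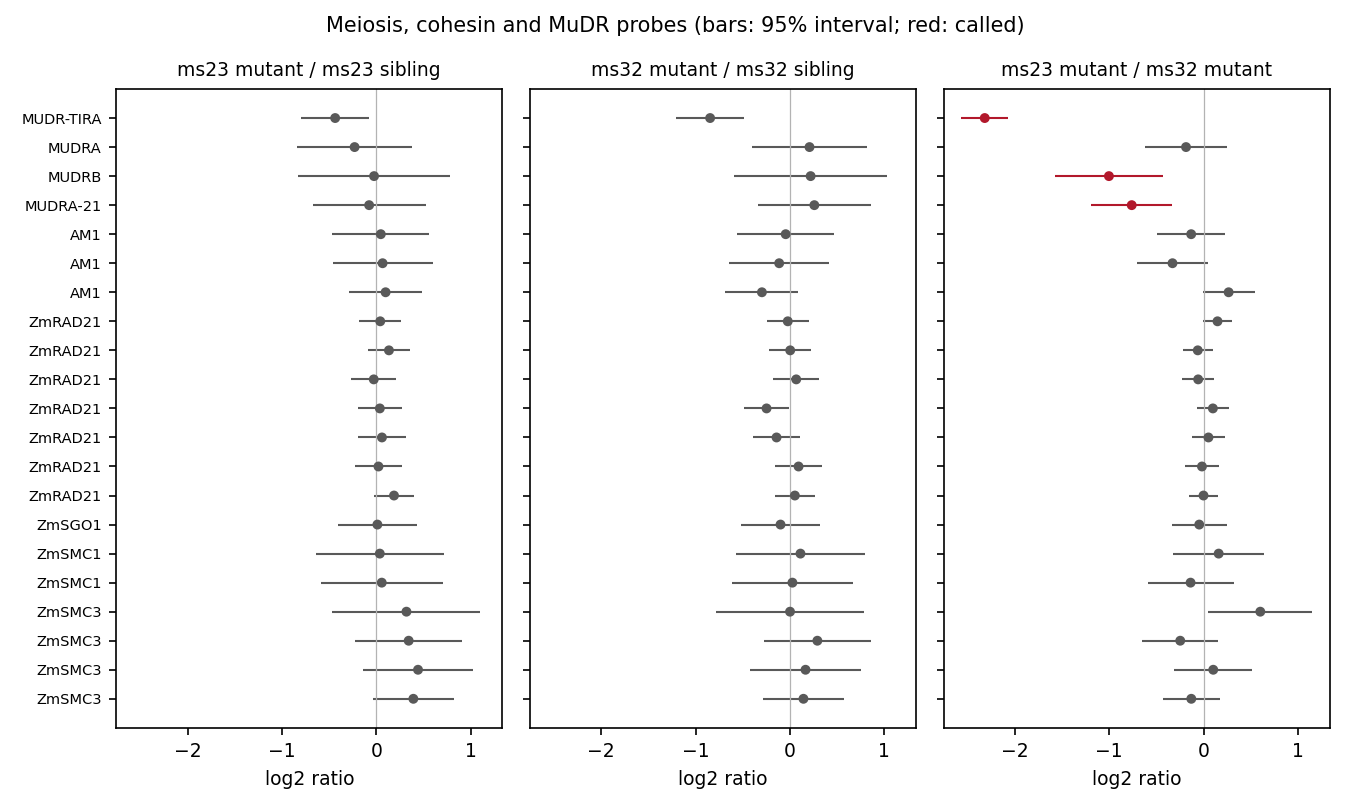
Points are log2 ratios of the probes named for meiotic, cohesin and MuDR genes in the 2 comparisons of mutant over sibling and in that of ms23 over ms32 mutants; bars are 95% confidence intervals and red marks called probes. Red points occur only in the direct comparison, at MUDR-TIRA, MUDRB and MUDRA-21.

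The effects of the 2 mutations were also tested against each other. They differed at 12 of 39969 probes (limma, adjusted p under 0.05), with 8 more positive in the ms23 family and 4 in the ms32 family; 2270 probes had an unadjusted p under 0.05. Of the 12, 7 had been called lower in ms32 mutants alone, 4 lower in ms23 mutants alone and 1 higher in ms23 mutants alone. DN227504 showed the largest difference, 8.71 on the log2 scale (SE 0.362, limma adjusted p = 0.0128): it fell by 7.35 in ms32 mutants and had a ratio of 1.37 in ms23 mutants that missed the threshold (limma adjusted p = 0.085). The direct ratio of the mutants for DN227504 was 6.73 (limma adjusted p = 2.72e-05). CF014920 fell by 3.59 in ms32 mutants and passed the test of the difference (limma adjusted p = 0.0335) through that family alone; it was well above background in 1 of 6 ms23 mutant and 0 of 2 ms23 fertile samples, so its ms23 effect and the size of the difference were not measurable.

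CF036691 differed by -4.05 (SE 0.184, limma adjusted p = 0.0128) and TC303557 by -3.94 (SE 0.231, limma adjusted p = 0.0281), and in ms23 mutants CF036691 fell by 4.11 and TC303557 fell by 3.81. CF036691 was well above background in both ms23 fertile but in only 1 of 6 ms23 mutant samples, so its fall ended at a level near background and its size is uncertain. Its ratio in ms32 mutants against siblings was -0.07. With a direct ratio near 0 as well, the ms32 samples may also have lain near background, with little room to show a fall. For these 2 transcripts the direct ratio of the mutants was near 0, at -0.11 for CF036691 and 0.05 for TC303557. Such a difference lies by construction in the fitted ratio between the fertile siblings, which had 1 replicate number per family. Among the 12 probes the direct ratio was called with the sign of the difference for 4, with the opposite sign for 2 and not called for 6. The count of 12 fell to between 0 and 3 whichever array was left out, to 0 in limma with a dye term per slide (2401 at an unadjusted p under 0.05) or with dye-swapped arrays averaged (2530), and ranged up to 64 with an intensity trend and robust variances.

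**Figure D4:**
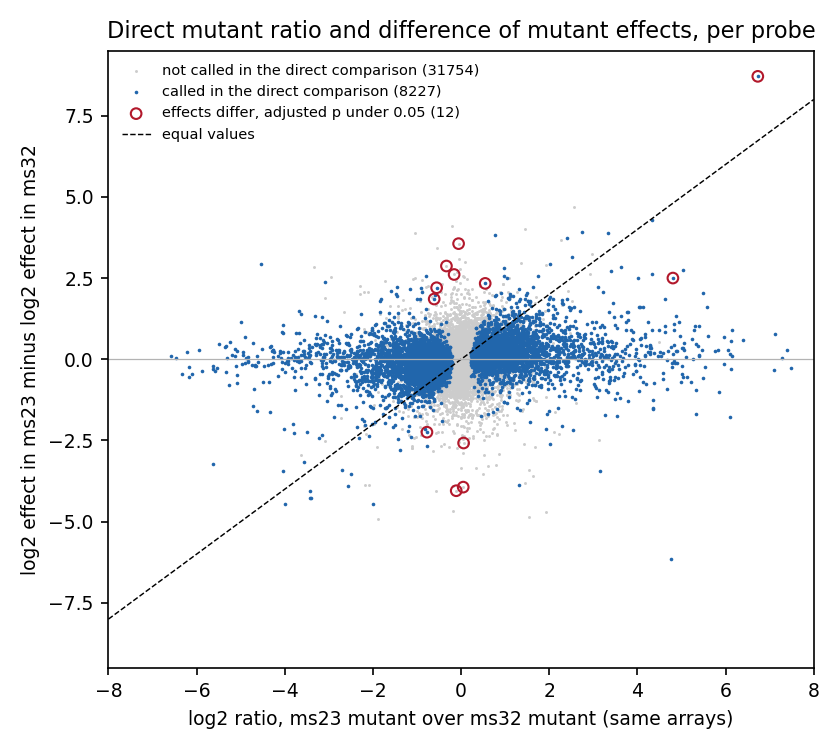
Each point is a tested probe, with the log2 ratio of ms23 over ms32 mutants measured on the same arrays on the horizontal axis and the difference of the 2 mutant effects against siblings on the vertical axis. Most of the 8227 probes called in the direct comparison (blue) lie along the horizontal zero line and not along the dashed line of equal values; circles mark the 12 probes whose effects differed.

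The fertile siblings of the 2 families were linked through the mutants, as the sum of 3 measured ratios, to ask how far the family backgrounds differ. This ratio equals the direct ratio of the mutants minus the difference of their effects, so a transcript with a large direct ratio and little change against siblings has a large ratio here by construction. TC298763 was higher in ms23 than in ms32 fertile siblings (limma adjusted p = 0.00233); it was well above background in both ms23 and in neither ms32 fertile sample, so no size is given, and it lost the threshold in 2 of 24 alternatives. AI737914, at -6.68 (SE 0.977, limma adjusted p = 0.0323), and TC304850, at -6.50 (SE 0.626, limma adjusted p = 0.0093), were lower, as was MUDR-TIRA at -2.73 (limma adjusted p = 0.00663); AI737914 lost the threshold in 11 of 25 alternatives, TC304850 in 6 and MUDR-TIRA in 5. The largest fitted rise among the called probes, that of TC280396 with a ratio of 7.86 (SE 1.29, limma adjusted p = 0.0458), rested on ms32 arrays of opposite sign, at 4.28 and -0.24, and lost the threshold in 12 of 24 alternatives.

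In all, 431 probes were higher and 397 lower in ms23 than in ms32 fertile siblings (limma, adjusted p under 0.05). With median centring 266 probes were higher and 730 lower, a share of lower probes of 73.3% in place of 47.9%, and with scaling between arrays 183 were higher and 86 lower (32%). Limma called 0 probes with dye-swapped arrays averaged (4702 at an unadjusted p under 0.05), 150, 162, 351 and 468 without slide 2 array 4, 3, 2 or 1, and 473 and 526 without slide 1 array 3 or 2.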

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

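Of the tests reported here, those of dye or slide artefacts, of the number of arrays, of different mutation effects, of single-probe variants and of the normalization over all calls were chosen only after the result was seen.

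Transcripts fell in both mutants: 103 probes were lower in both against 1.69 for independent lists. That expectation may be too low, because both lists used the same variance for each probe. A dye or slide artefact not tied to the RNA would give opposite signs on arrays of opposite dye orientation, but ms23 and ms32 arrays of opposite orientation correlated across probes at 0.228 or higher. A biological effect common to both mutations may account for the shared loss, and it stays untested because no list of cell-type genes had enough measured members.

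The mutants differed from each other at 8227 probes, far more than either differed from its siblings, and the number of arrays does not explain this as the sole cause, since 1891 probes were still called with 2 arrays, against 45 for the ms23 mutant and its siblings in the same fit. Different effects of the 2 mutations do not explain most of it, since the difference of the effects against siblings had a slope of 0.112 on the direct ratio (0.103 to 0.12), where 1 would be needed. This slope was taken over probes called in the direct comparison, and over all tested probes it was 0.123. The interval runs across probes, which are not independent replicates, so it does not measure the spread between plants. A second probe had the sign of the called one for 70.8% of 596 transcripts (67% to 74.4%), against 91.1% of 45 for ms23 mutants and siblings, so sequence variants under single probes may account for a part and stay open. The calls of the direct comparison were also smaller, with median log2 ratios of 0.82 and -0.75 against 1.37 and -1.83. The gap between the 2 shares therefore cannot decide this. The other ways of assigning the samples within the 4 arrays number too few for a share under 0.05, with 8227 probes called by the real one and 3 by the highest of the others. The fertile siblings also differed, at 828 probes in an indirect ratio that contains the direct one; whether genetic background or anther stage lay behind the difference between families was not tested and stays open.

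Falls outnumbered rises among the calls against the fertile siblings. In ms23 mutants the share of falls among the calls dropped to 35% with median centring, and to 36.3% among changes of at least 2-fold. With every other normalization tried it stayed between 63.5% and 74.8%, and between 67.7% and 74.8% among changes of at least 2-fold. The excess of falls there was therefore lost with median centring alone, and whether the within-array normalization accounts for it stays open. In ms32 mutants the lowest share over the other normalizations was 89.6%, which argues against that explanation for this family.

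A single ms32 mutant sample stood apart: its median spot intensity on slide 1 array 4 (Cy5) was 232.25, against 116 to 140 in the other 5 samples of its group. It was the 1 such value among 26 groups of values examined, and chance gives about 1 in 20.

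The effects of the 2 mutations differed at 12 probes by a test of the difference. The direct ratio of the mutants was called with the sign of the difference for 4 of them, with the opposite sign for 2 and not called for 6. Where the direct ratio is near 0, the difference lies by construction between the fertile siblings, which had 1 replicate number per family. DN227504 differed by 8.71, CF036691 by -4.05 and TC303557 by -3.94 on the log2 scale, ms23 minus ms32 (limma adjusted p = 0.0128, 0.0128 and 0.0281). CF014920 had a fitted difference of 3.56 (limma adjusted p = 0.0335) that is not a measured size, since it was well above background in 1 of 6 ms23 mutant and 0 of 2 ms23 fertile samples. The other 11 of the 12 probes were well above background in at least 50% of the samples of a group in each family. When only probes well above background in all samples were tested, limma called 1 probe for the difference. CF036691 was well above background in 1 of 6 ms23 mutant samples, so its size is uncertain. Its direct ratio was -0.11 and its ratio in ms32 mutants against siblings -0.07. The ms32 samples may therefore also have lain near background, with little room to show a fall.

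Control spots outside the comparisons carried strong signal. The E1A spots, 320 in 10 kinds, had a highest median Cy3 intensity of 12180.5 on an array and a lowest of 3929, where the negative controls lay between 39.5 and 44. Mean log2 ratios of Cy5 over Cy3 of the 10 kinds ranged from -3.07 to 2.47, with SDs over the arrays of 0.548 to 0.861.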

How the results depend on the processing

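The fits with slide 1 arrays 1 and 2, 3 and 4, or 2 and 3 beside slide 2, and the crossed replicate block, were tests chosen only after the result was seen. In the order ms23 mutant versus sibling, ms32 mutant versus sibling, direct comparison, difference of effects, sibling ratio and calls shared by both mutants, the counts were 525, 196, 8227, 12, 828 and 110. They were the same with no replicate block (each array independent), because the estimated correlation was below 0, and with the crossed replicate block.

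Averaging dye-swapped arrays, which leaves 1 residual degree of freedom, gave 34, 0, 4392, 0, 0 and 0. Slide 2 alone, also with 1, gave 0 and 0 for the mutants against siblings, 0 for the difference and 0 shared; slide 1 alone gave 5929 in the direct comparison. With fewer slide 1 arrays, the counts in that order were 45, 26, 1891, 0, 179 and 19 (arrays 1 and 2), 56, 54, 2778, 1, 104 and 34 (arrays 3 and 4) and 72, 56, 3084, 0, 376 and 36 (arrays 2 and 3). Wherever limma called 0 probes in a single comparison, 1432 to 4702 had an unadjusted p under 0.05.

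For the settings above and below the cause of the change was not tested. An offset of 10 gave 298 for ms32, 20 for the difference and 167 shared. An intensity trend with robust variances gave 310 for ms32, 64 for the difference and 172 shared. Scaling between arrays gave 928 for ms23, 22 for the difference and 269 for the siblings. A dye term per slide gave 129 for ms32 and 0 for the difference, and no dye term 22 for the difference. The difference had 4 calls with the scanner software's processed signals, 4 with median centring and 7 with the deposited processed table. Testing only probes well above background in all samples gave 1 for the difference and 516 for the siblings. All other counts stayed within 1.5 times the reported one.

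With each array left out in turn, counts ranged from 48 to 531 for ms23, 67 to 140 for ms32, 4459 to 8058 for the direct comparison, 0 to 3 for the difference, 150 to 679 for the siblings and 36 to 80 for the shared calls. Leaving out an array of a mutant and sibling pair leaves 1, whose spread is assumed to be like that of the others. The lowest values for ms23, the siblings and the shared calls came without slide 2 array 4, for ms32 without slide 2 array 1 and for the direct comparison without slide 1 array 3.

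Over the 91 results for named probes, 2339 values under alternatives were computed: 2161 stayed on their side of the threshold, 178 kept the direction but lost the threshold, and 0 of the called results changed direction. Most of the 91 results were not called and so had no threshold to lose. All 178 losses fell among the called results, so the pooled count says little about how stable those were. The direct ratios of TC298763, TC280899, AI737914, TC304850 and MUDR-TIRA passed under every alternative that measured them, whereas TC295588 lost the threshold in 11 of 26, TC280520 in 9, TC299638 in 8, TC310653 in 14 of 26 and TC313690 in 18 of 25. The differences of effects lost it in 11 of 26 for DN227504, and of 25 in 17 for CF014920 and in 14 each for CF036691 and TC303557. Alternatives for the gene lists were not run, since no list had enough measured genes. Signal was 2.68 to 6.11 times the background, and 2053 probes were too dim to be tested.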

Other observations

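The tests of the ms23-only probes below were chosen only after the result was seen.

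Among the probes that rose in ms23 mutants, 77 of 154 were also called higher in ms23 than in ms32 mutants on slide 1, where independent lists would share 14.7, and 20 were called lower, against 17. Of the 14 probes higher in ms32 mutants, 11 were called lower in that direct comparison, against 1.55 for independent lists, whereas of the 182 lower there 25 were called higher and 19 lower, against 17.3 and 20.1. Of the 371 probes lower in ms23 mutants, 71 were called lower in the direct comparison and 40 higher, against 41.1 and 35.3. The direct comparison used other samples of the mutants than the comparisons with siblings. All lists used the same variance for each probe, however, so the counts for independent lists may be too low.

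A hypothesis was that the 147 rises and the 268 falls called in ms23 mutants alone belong to that mutant. The median direct ratio over the 147 rises was 0.424, further from 0 than in any of 10000 random sets matched on intensity (-0.111 to 0.0946), and that over the 268 falls was -0.0755, where 5 of 10000 sets lay as far (-0.0393 to 0.0607). The random sets were matched on intensity alone and their probes were drawn independently, so these ranges may be too narrow. Both medians went the way of the change against siblings and stayed short of 50% of it, 0.69 for the rises and -0.781 for the falls, so the hypothesis stays open for both sets. The rises came much nearer to that mark than the falls. Of the 268 falls, 112 had a positive direct ratio, and of the 147 rises 37 had a negative one. Differences between the fertile siblings could also enter these sets, because each was chosen on a ratio to a sibling. The fitted ratio of ms23 over ms32 fertile siblings had a median of 0.804 over the 268 falls, with 232 positive. Over the 147 rises its median was -0.428, with 110 negative.

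Transcripts represented by assembled contigs were called more often than the rest in the direct comparison. Of 26470 probes for tentative consensus contigs, 13.4% were lower and 10.6% higher in ms23 than in ms32 mutants, against 6.49% and 7.39% of the other probes. The same held for ms23 mutants against siblings, with 1.07% lower and 0.476% higher, against 0.659% and 0.207% of the others. For ms32 mutants against siblings the shares were 0.48% and 0.0416%, against 0.407% and 0.0222% (Fisher test, adjusted p = 0.741 and 0.816). The contig probes and the others were not matched on intensity, and whether brightness lay behind the gaps was not tested. The log ratios of ms23 and ms32 arrays against siblings correlated across probes at 0.355 and 0.427 for the same dye orientation and at 0.228 and 0.37 for the opposite one, each above the 0.132 of the 2 ms32 arrays with each other. Probes are not independent replicates. The dye term was not taken out of these ratios. A dye effect raises the correlation for the same orientation and lowers it for the opposite one, which the 2 ms32 arrays had.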
